A study of Mus musculus with 35 samples.

How the data were processed

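RNA sequencing of mouse heart apex was used, from 35 libraries in 6 groups: sham and TAC hearts of WT, IRS1KO and IRS2KO mice. Groups were taken from the sample labels. Total RNA was isolated with mirVana reagents and made into stranded, poly(A)-selected libraries with a TruSeq kit, per the labels' protocols. The deposited table holds a normalized count signal for each of 27012 genes and each library, per the file headers. HISAT2 2.0.6, HTSeq 0.7.1, DESeq2 without a version and the mouse build GRCm38 are named, per the submitters' processing notes, which give no role or order. The version of the gene annotation is not given in the sources used here. Symbols, coordinates and gene types were taken from the GENCODE vM21 annotation of GRCm38, which held 26904 of the identifiers (99.6%), and 126 genes had no symbol.

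The deposited signal of each library was a whole multiple of 1 value for 100% of the genes within a tolerance of 0.001, so the reads counted per gene could be recovered. They came to 11707111 to 14609467 per library. The factors between reads and deposited values were those of DESeq2's median-of-ratios scaling over the 14547 genes above 0 in every library. No gene in the table had fewer than 2 recovered reads over all libraries. The lowest chi-square per degree of freedom between libraries of 1 group was 2.59, over 85 pairs, so no pair agreed within sampling noise and every library was counted separately. Y-linked genes were expressed in all 35 libraries.

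The test was limma (version 3.58.1 in R 4.3.3, with trend and robust options) on log2(value + 1), for the 13695 genes with a mean deposited value of at least 10 over all libraries. A single model held a mean for each of the 6 groups, and 12 contrasts were taken from it: TAC against sham in each genotype, each pair of genotypes within sham and within TAC, and the 3 differences of the TAC response. All 6 groups shared the estimate of the spread. Tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method within a contrast, with a threshold of 0.05. A log2 fold change is on the log2(value + 1) scale, which understates the change of low genes. Folds given in words are ratios of group means, and none is given where a group mean is under 3. SE is that of the fitted log2 fold change, and n is 6 libraries per group and 5 for WT TAC.

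There were 33 gene lists: cardiac stress and fetal genes, calcium handling and ion channels, cardiomyocyte structural genes, immediate early genes, extracellular matrix and fibrosis, cytokines and chemokines, cell cycle, fatty acid uptake and oxidation, nuclear oxidative phosphorylation genes, tricarboxylic acid cycle, glycolysis, mitochondrial genome mRNAs, mitochondrial biogenesis regulators, insulin and IGF signalling, FoxO targets, autophagy and lysosome, unfolded protein and integrated stress response, p53 targets, antioxidant response, interferon-stimulated genes, circadian genes and glucocorticoid-responsive genes, and markers of fibroblasts, macrophages, neutrophils, T and NK cells, B cells, endothelium, smooth muscle and pericytes, atrium, adipocytes, erythroid cells and mesothelium. They were tested with camera at a preset correlation of 0.01, adjusted over the lists within a contrast, and again with an estimated correlation. The 29 lists with at least 3 members above the filter were tested.

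Genes were named by a rule. It took Irs1 and Irs2, then in each contrast the 10 largest rises and the 10 largest falls past the threshold with a mean of at least 100 in the higher group, leaving out predicted names, Y-linked genes and Xist. It also took up to 4 called members of each list, or the 2 with the smallest p where none was called, and 16 genes of cardiac stress and metabolism that were open to naming throughout. Not every gene that this rule took is reported here. The groups, contrasts, test, gene lists, this rule and all alternatives but 1 were chosen before the data were examined.

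The alternatives were pseudocounts of 0.5 and 5, no filter, a mean of at least 50, the same total per library, quantile normalization, only the groups in the contrast, library weights (arrayWeights), the replicate number as a block, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, fry in place of camera, and leaving out each library in turn. The alternative without the 3 TAC libraries nearest to sham was chosen after seeing the data. A sex covariate was planned and not run, since all libraries expressed Y-linked genes. Correlations of effects that share the WT libraries were set beside 100 simulations of unchanged groups, and each count of calls beside 100 splits of the same libraries.

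The scripted steps were tested on simulated data for 13695 genes with 200 changed. For IRS1KO against WT in sham, limma recovered 70% of 1.5-fold and 87% of 2-fold changes, with 3 false among 160 calls. For IRS1KO against WT after TAC it recovered 49% and 74%, with 44 false among 167 calls, and 32% and 66% with 4 false among 102 when only those groups were fitted. For TAC against sham in WT it recovered 56% and 86%, with 16 false among 158 calls. For the difference of the TAC response between IRS1KO and WT it recovered 21% and 63%, with 3 false among 87 calls.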

Results

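Messenger RNA was sequenced from the apex of the heart of mice, 3 days after transaortic constriction (TAC, a surgical narrowing of the aorta that raises the pressure load on the left ventricle) or after a sham operation. The mice were operated on at 6 weeks of age and carried 1 of 3 genotypes. WT mice had a floxed Irs2 gene and no Cre recombinase, IRS1KO mice had a floxed Irs1 gene with the cardiomyocyte-specific alphaMHC-Cre, and IRS2KO mice had a floxed Irs2 gene with the same Cre. Each genotype and operation had 6 libraries, except WT TAC with 5. Each library held between 11707111 and 14609467 reads assigned to genes, and between 18599 and 20803 genes were detected per library. Group values below are means of normalized counts ± SD over these libraries (n = 6, or n = 5 for WT TAC). Because the labels do not say that each library came from a separate mouse, the p-values measure the spread between these libraries. No library with Cre alone was among the groups, and none carried the floxed Irs1 gene without Cre.

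Irs1 and Irs2 encode insulin receptor substrates, the adaptor proteins through which the insulin and IGF1 receptors activate PI3 kinase. Irs1 (chromosome 1, 82233101 to 82291416 in GRCm38) stood at 233 ± 52.5 in WT sham hearts and at 25.9 ± 15.1 in IRS1KO sham hearts, which is 11.1% of the WT level. After TAC it stood at 181 ± 40.6 in WT and 27.4 ± 27.4 in IRS1KO, 15.2% of WT. Every IRS1KO library lay below every WT library of the same operation (limma adjusted p = 0.00043 in sham and 0.0025 after TAC, 0.0656 after TAC when only those groups were fitted). IRS1KO TAC replicate 5 was the highest of its group at 80.3, and the other 5 averaged 16.8. Irs1 was not past the threshold in either comparison of IRS2KO with WT, at 244 ± 31.1 in sham and 237 ± 78.1 after TAC.

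Irs2 (chromosome 8, 10984681 to 11008458) stood at 123 ± 14.4 in IRS2KO sham and 121 ± 41.2 in IRS2KO TAC hearts, 56.8% and 50.4% of the WT means of 217 ± 174 and 239 ± 68.6. Neither difference passed the threshold (limma adjusted p = 1 and 0.695), and the WT sham mean rested in part on replicate 2, at 564 against at most 195 in the other 5. Those 5 averaged 148, much nearer to the IRS2KO sham mean of 123. Without that library, the Irs2 level of IRS1KO sham hearts, 317 ± 101, passed the threshold against WT (adjusted p = 0.0375, against 0.246 with all libraries). Reads from outside the deleted part of each gene, and from cells other than cardiomyocytes, still count toward these values.

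**Figure D1:**
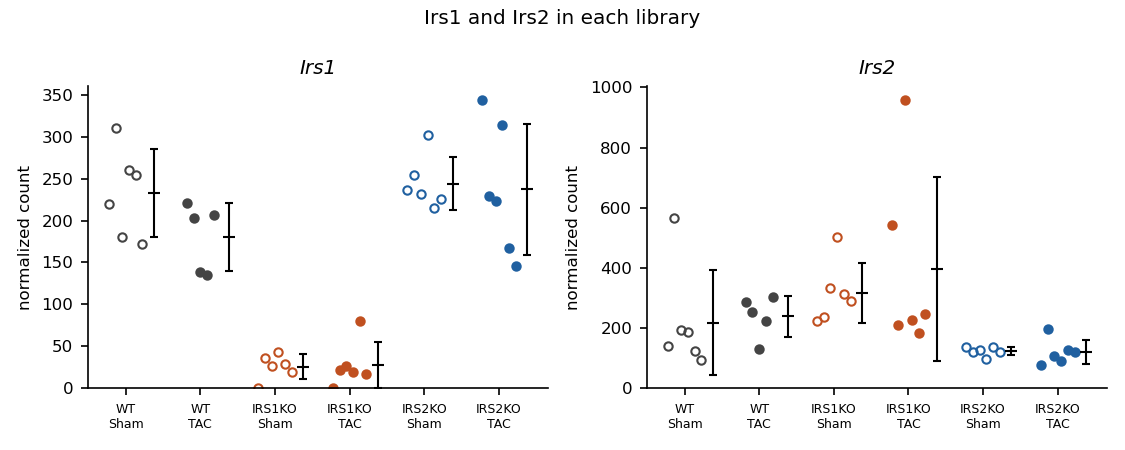
Normalized counts of Irs1 (left) and Irs2 (right) in each library; open circles are sham and filled circles TAC libraries, and the bars beside them give the group mean ± SD (n = 6, or 5 for WT TAC). Irs1 reaches at most 80.3 in the IRS1KO libraries and at least 135 in the WT libraries, while the Irs2 levels of IRS2KO and WT libraries overlap.

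The first comparison asked what pressure overload did to the WT heart after 3 days. TAC raised genes of cardiomyocyte stress, extracellular matrix, inflammation and cell division, and lowered genes of mitochondrial energy metabolism. The RNA came from apex tissue as a whole. Here and below, changes within cardiomyocytes therefore cannot be told from changes in the mix of cells. Sprr1a, a small proline-rich protein induced in stressed cardiomyocytes, went from 2.68 ± 3.97 (1.09 without replicate 6) to 2150 ± 1804, and Spp1, which encodes the matrix protein osteopontin, from 2.84 ± 1.66 to 4357 ± 4659 (2441 without replicate 3). Nppa, which encodes atrial natriuretic peptide, rose 14.2-fold from 594 ± 129 to 8452 ± 2927 (limma log2 fold change 3.80, SE 0.24, adjusted p = 9.8e-14). All 13 measured members of the cardiac stress and fetal list rose, among them Nppb 7.42-fold, Rtn4 6.09-fold and the titin-binding Ankrd2 19.1-fold (12.1-fold without WT TAC replicate 5). All 27 genes of the extracellular matrix and fibrosis list rose too, with a median log2 fold change of 3.19. The matrix glycoprotein Tnc rose 194-fold, and the metalloproteinase inhibitor Timp1 74.2-fold. Both lists passed camera with the preset correlation (adjusted p = 2.5e-09 and 2.8e-26) and neither did with an estimated one (adjusted p = 0.162 with an estimated correlation for both).

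Of 17 macrophage and monocyte markers 16 rose after TAC in WT hearts, including Lgals3 (42.7-fold), the chemokine receptor Ccr2 (35.6-fold) and Cx3cr1 (12.3-fold). Of 13 cytokine, chemokine and acute inflammation genes 12 rose, with Ccl2 at 234 ± 210 against 5.85 ± 3.00. Il1rn stood at 299 ± 298 (197 without replicate 3) against 1.95 ± 1.30, above every sham library in 4 of 5 TAC libraries. Cxcl5 was listed at 0 in every sham library and averaged 56.2 ± 75.5 after TAC (23.6 without replicate 1). The adjusted p was 1.1e-09 for the macrophage list and 4.7e-07 for the cytokine list (adjusted p = 0.162 and 0.163 with an estimated correlation). The macrophage products Chil3 (155 ± 143) and Arg1 (223 ± 230, and 140.4 without replicate 1) were near 1 count in sham hearts. Cell cycle genes rose in 22 of 24 cases, and in 24 adjusted over the list alone, with the mitotic cyclin Ccnb1 33.9-fold higher and the list median at 3.31 (adjusted p = 4.8e-16, and adjusted p = 0.163 with an estimated correlation). Fibroblast markers went both ways, 8 up and 1 down of 12 (adjusted p = 0.00567, and adjusted p = 0.241 with an estimated correlation). The transcription factor gene Meox1 rose 5.39-fold and Mfap4 3.96-fold.

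Smaller rises covered 3 more lists. Of 15 immediate early genes 9 rose, with Egr2 21.4-fold and Fos 4.57-fold higher (adjusted p = 0.00234, and adjusted p = 0.426 with an estimated correlation). Of 23 unfolded protein and integrated stress response genes 15 rose and 3 fell, or 16 and 4 adjusted over the list alone (adjusted p = 0.00459, and adjusted p = 0.426 with an estimated correlation). The stress hormone gene Gdf15 rose 23.9-fold and Mthfd2, an enzyme of mitochondrial one-carbon metabolism, 6.18-fold. Of 9 antioxidant genes 5 rose and 1 fell, or 6 and 1 adjusted over the list alone, led by the haem oxygenase gene Hmox1 at 13.2-fold and Gpx3 at 2.82-fold (adjusted p = 0.00616, and adjusted p = 0.395 with an estimated correlation).

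Genes of energy metabolism fell together in the WT heart after TAC. Of 26 fatty acid uptake and oxidation genes 24 fell, with a median log2 fold change of -0.96, among them the thioesterase gene Acot1 (3.64-fold lower) and Hadh of beta-oxidation (2.24-fold). Of 41 nuclear oxidative phosphorylation genes 38 fell, and 40 adjusted over the list alone, with a median of -0.60; the cytochrome oxidase subunit genes Cox7a1 and Cox8b were 1.92-fold and 1.78-fold lower. All 17 tricarboxylic acid cycle genes fell (median -0.57), with Idh2 2.09-fold and Suclg2 1.66-fold lower. The adjusted p of these 3 lists was 9.1e-08, 3.8e-09 and 1.4e-05 (adjusted p = 0.426 with an estimated correlation for each). The mRNAs of the mitochondrial genome fell in 12 of 13 cases, and in 13 adjusted over the list alone (adjusted p = 0.00234, adjusted p = 0.426 with an estimated correlation, and 0.24 with quantile normalization), with mt-Atp6 1.57-fold lower. Reads from the mitochondrial genome made up 29.9% ± 0.51 of all reads in WT sham and 23.4% ± 2.19 in WT TAC libraries. Of 12 mitochondrial biogenesis regulators 8 fell, or 9 adjusted over the list alone, with Perm1 1.61-fold and Esrrg 1.59-fold lower (adjusted p = 0.00992, and adjusted p = 0.426 with an estimated correlation).

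Other lists that fell in WT were the FoxO targets, 13 of 16 (Gadd45a 2.68-fold and Klf15 1.85-fold lower; adjusted p = 0.000763, and adjusted p = 0.41 with an estimated correlation), and the endothelial markers, 7 of 12 (Flt1 1.53-fold and Tie1 1.42-fold lower; adjusted p = 0.00525, and adjusted p = 0.426 with an estimated correlation). Of 15 circadian genes 9 fell and 3 rose, or 10 and 3 adjusted over the list alone, with Hlf 3.39-fold and Per3 2.64-fold lower and Arntl 2.63-fold higher (adjusted p = 0.026, adjusted p = 0.405 with an estimated correlation, and 0.0713 with quantile normalization). All 5 erythroid markers fell, among them the haem synthesis gene Alas2 by 1.03 on the log2 scale (adjusted p = 0.0419, adjusted p = 0.426 with an estimated correlation, and 0.0907 with quantile normalization). The erythroid call ended without WT sham replicate 2 (0.0696) or 6 (0.0605), or without WT TAC replicate 1 (0.0891) or 2 (0.059). Single genes with large falls were the carboxylesterase gene Ces1d (8.21-fold, from 876 ± 127 to 107 ± 86.2), Klhl33 (7.51-fold), the sodium channel subunit gene Scn4b (5.22-fold) and the kinase gene Mylk4 (4.73-fold).

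The remaining lists did not pass the list test in WT, although many of their members moved. Of 16 calcium handling and ion channel genes 11 fell and 4 rose (adjusted p = 0.0963), with the potassium channel subunit gene Kcnip2 2.82-fold and Atp2a2, the calcium pump of the sarcoplasmic reticulum, 1.87-fold lower. Of 16 cardiomyocyte structural genes 11 fell and 1 rose (adjusted p = 0.0554, and 0.0125 for both lists with the same total per library); Tcap and Mb were 2.09-fold and 1.97-fold lower, and Des was 2.02-fold higher. This list passed without WT TAC replicate 2 (0.0293) or 5 (0.0477), and the interferon-stimulated list (5 of 14 up, Mx1 8.61-fold, or 4.21-fold without WT TAC replicate 3, and Oas1a 2.92-fold; adjusted p = 0.0963) passed without WT TAC replicate 1 (0.0335) or 5 (0.0206). Among 32 insulin and IGF signalling components 6 rose and 13 fell, or 6 and 14 adjusted over the list alone (adjusted p = 0.255), with Igf1 3.67-fold higher and the glucose transporter gene Slc2a4 1.76-fold and the adaptor gene Grb14 1.86-fold lower. Among 18 glycolysis genes 8 rose and 5 fell (adjusted p = 0.529), with the lactate transporter gene Slc16a3 7.74-fold and Pgam1 2.29-fold higher and Pfkfb2 1.96-fold lower. The median of this list was -0.07 and its mean 0.25, so the test (up) and the median differ in sign. Among 11 smooth muscle and pericyte markers 3 rose and 6 fell (adjusted p = 0.299), with Cnn1 15.8-fold higher and Abcc9 2.31-fold lower; here too the mean (0.04) differs in sign from the test (down), as it did in IRS1KO (0.07) and IRS2KO (0.18). With the same total per library the medians of the smooth muscle, glycolysis and insulin lists were above 0 (0.0045, 0.19 and 0.16). Autophagy and lysosome genes went up in 4 and down in 2 of 16 cases, or 3 and 2 adjusted over the list alone (adjusted p = 0.421; Ctsb 2.00-fold higher). Among 12 p53 targets 4 rose and 1 fell (adjusted p = 0.199; Phlda3 2.58-fold higher), and among 8 glucocorticoid-responsive genes 2 rose and 2 fell (adjusted p = 0.918; Mt2 3.53-fold higher, Pdk2 1.94-fold lower). Of 3 atrial markers 1 fell (Stard10 2.24-fold; adjusted p = 0.251), and none of 3 mesothelial markers was called (adjusted p = 0.655). Counts adjusted over the list alone equalled the all-gene counts wherever none is given. The neutrophil, T and NK cell, B cell and adipocyte lists had 2, 1, 1 and 0 members above the filter and were not tested; Csf3r of neutrophils was 7.11-fold and Blk of B cells 2.24-fold higher after TAC.

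**Figure D2:**
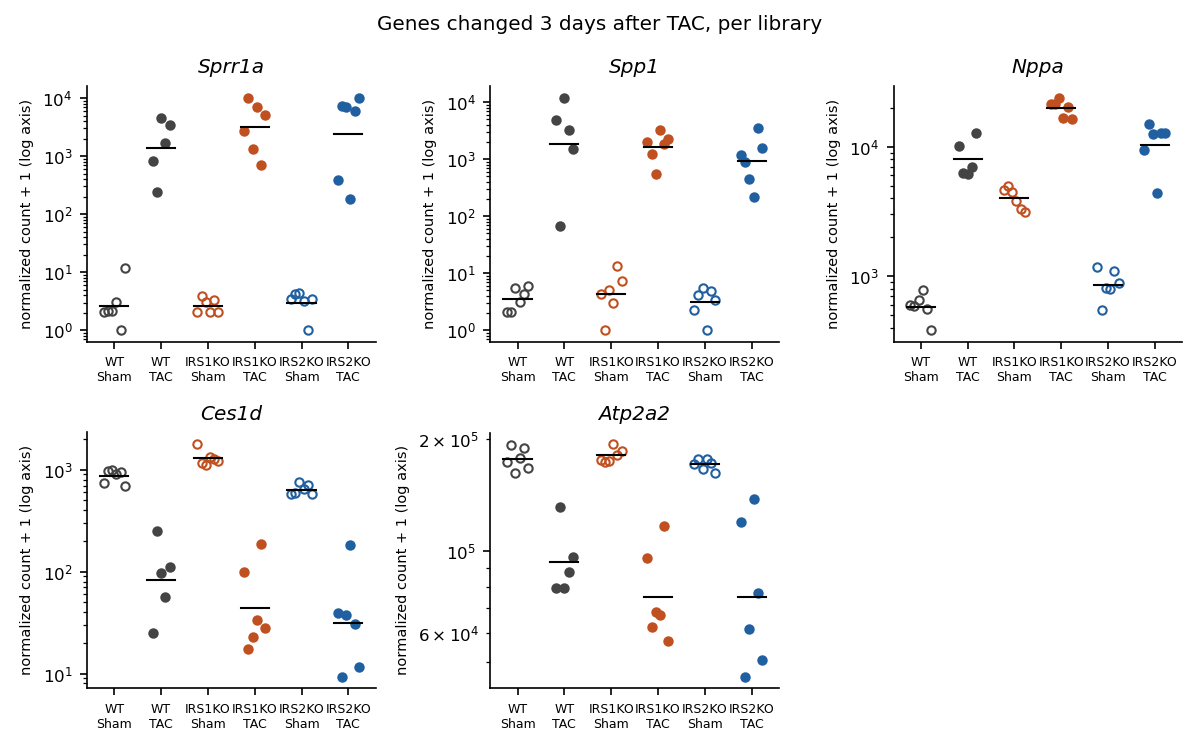
Normalized counts plus 1 of 5 genes in each library, on log axes; open circles are sham and filled circles TAC libraries, and each line is the mean of the log2 values. In every genotype all TAC libraries lie above all sham libraries for Sprr1a, Spp1 and Nppa and below them for Ces1d and Atp2a2.

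In total 3877 of 13695 genes rose and 3638 fell in WT after TAC (adjusted p under 0.05, limma). With every library scaled to the same total, the median gene moved by 0.24 and the calls split into 6221 higher and 1583 lower, 79.7% higher in place of 51.6%. Leaving out 1 library at a time moved no other call named here for WT, and 149 of the 165 results for single genes in the 3 comparisons of TAC with sham had every TAC library beyond every sham library.

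The same comparison was made in the IRS1KO genotype. In IRS1KO hearts 4442 genes rose and 4335 fell after TAC (7181 and 2164, 76.8% in place of 50.6% higher, with the same total per library). Sprr1a went from 1.73 ± 0.80 to 4539 ± 3672, Spp1 from 4.67 ± 4.33 to 1860 ± 931 (398-fold) and Tnc from 19.2 ± 7.67 to 6483 ± 2231 (338-fold). The collagen gene Col11a1 went from 1.52 ± 1.25 to 355 ± 205. Nppa rose 4.94-fold from 4045 ± 746 to 19972 ± 2936. All 13 stress genes, all 27 matrix genes and all 24 cell cycle genes rose, with list medians of 2.00, 3.56 and 3.76; Top2a was 34.1-fold and Ccnb1 43.8-fold higher. Of 17 macrophage markers 14 rose and 1 fell, with Lgals3 27.7-fold and Ccr2 22.3-fold higher, and of 13 cytokine genes 12 rose. The adjusted p of these 5 lists was 9.7e-08, 1.7e-21, 2.6e-14, 1.6e-06 and 0.000149 (adjusted p = 0.345 with an estimated correlation for each).

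All 26 fatty acid genes, all 41 oxidative phosphorylation genes and all 17 tricarboxylic acid cycle genes fell in IRS1KO hearts after TAC, with medians of -1.28, -0.93 and -0.89 and adjusted p of 1.3e-09, 1.4e-13 and 5.9e-07 (adjusted p = 0.345 with an estimated correlation for each). Acot1 was 5.11-fold, the uncoupling protein gene Ucp3 4.34-fold, Cox7a1 2.92-fold and Idh2 2.87-fold lower. Reads from the mitochondrial genome went from 28.6% ± 1.23 to 19.5% ± 3.22 of all reads. Of 12 endothelial markers 11 fell (Kdr 1.97-fold and Tie1 1.82-fold; adjusted p = 0.000149, and adjusted p = 0.345 with an estimated correlation). Ces1d fell 20.8-fold from 1317 ± 240 to 63.4 ± 66.4 (33.6-fold without TAC replicate 5), the ion channel subunit gene Cngb3 13.2-fold, Lgals4 9.99-fold and Kcnip2 5.56-fold. Among insulin and IGF signalling components 9 rose and 10 fell, or 9 and 9 adjusted over the list alone (adjusted p = 0.788), with Igf1 3.73-fold higher and Slc2a4 2.33-fold lower. In all, 9 lists passed upward and 10 downward with the preset correlation, and 0 did with an estimated one.

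In IRS2KO hearts 4286 genes rose and 4260 fell after TAC (7438 and 1890, 79.7% in place of 50.2% higher, with the same total per library). Sprr1a went from 2.26 ± 1.21 to 5125 ± 3977, Spp1 from 2.53 ± 1.68 to 1318 ± 1205 (870 without TAC replicate 5), and Nppa rose 12.5-fold from 888 ± 226 to 11125 ± 3734. Tnc was 288-fold and the collagen gene Col12a1 59.7-fold higher. All 13 stress genes, all 27 matrix genes and all 24 cell cycle genes rose, with medians of 2.08, 3.08 and 3.55, and adjusted p of 1.2e-08, 1.2e-21 and 5.8e-15 (adjusted p = 0.258, 0.258 and 0.308 with an estimated correlation). Of 17 macrophage markers 14 rose, and 1 fell adjusted over the list alone (adjusted p = 1.3e-06, and adjusted p = 0.324 with an estimated correlation), with Ccr2 36.7-fold and Lgals3 28.1-fold higher. Of 13 cytokine genes 11 rose, among them Ccl2 41.1-fold (adjusted p = 4.0e-05, and adjusted p = 0.324 with an estimated correlation).

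All 26 fatty acid, 41 oxidative phosphorylation and 17 tricarboxylic acid cycle genes fell in IRS2KO hearts after TAC, with medians of -1.36, -0.88 and -0.81 and adjusted p of 3.1e-11, 4.8e-13 and 2.3e-07 (adjusted p = 0.352, 0.364 and 0.364 with an estimated correlation). Pdk4, the kinase that holds pyruvate dehydrogenase inactive, fell 5.70-fold from 32820 ± 5530 to 5759 ± 2298, Ucp3 5.46-fold and Acot1 5.40-fold (8.54-fold and 8.42-fold without TAC replicate 4). The transcriptional coactivator gene Ppargc1a was 2.52-fold lower. Of 16 FoxO targets 13 fell, and 1 rose adjusted over the list alone, with Klf15 3.34-fold and Sesn1 3.16-fold lower (adjusted p = 2.5e-05, and adjusted p = 0.324 with an estimated correlation). Among insulin and IGF signalling components 6 rose and 16 fell, or 7 and 17 adjusted over the list alone (adjusted p = 0.104), with Igf1 4.30-fold higher and Foxo3 2.39-fold lower. Reads from the mitochondrial genome went from 30.4% ± 0.75 to 21.1% ± 4.91 of all reads. In all, 10 lists passed upward and 10 downward with the preset correlation and 0 with an estimated one.

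**Figure D3:**
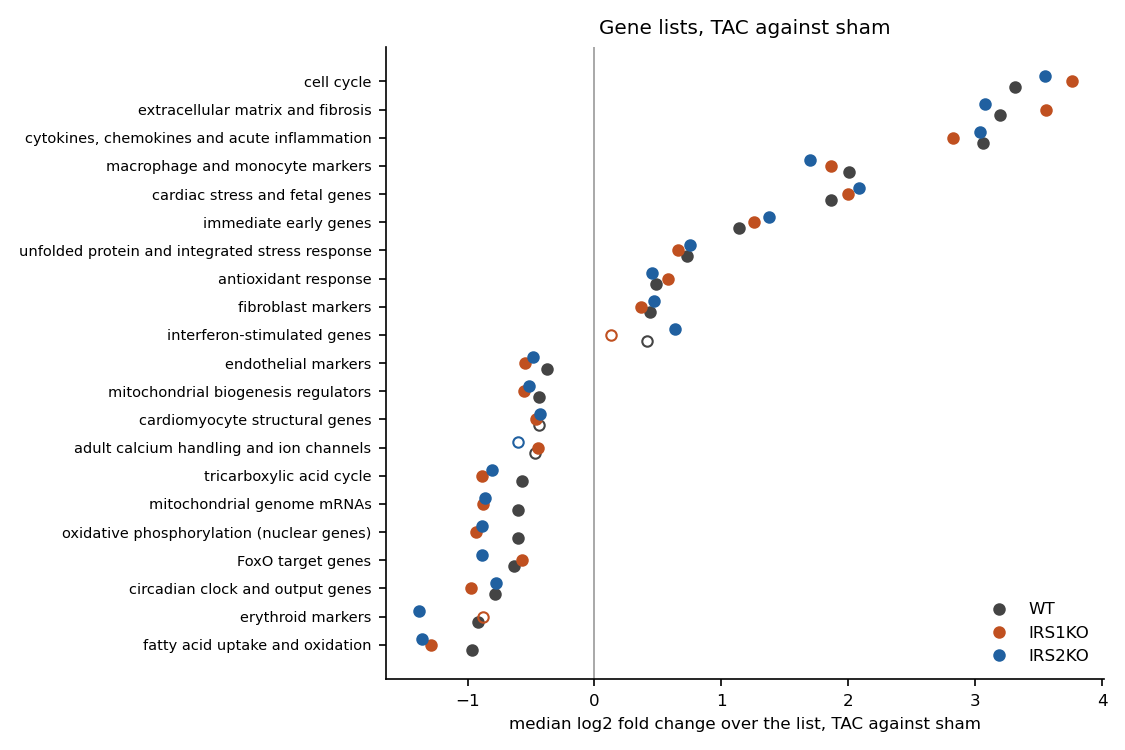
Median log2 fold change, TAC against sham, of each fixed gene list that passed the list test in at least 1 genotype; filled circles passed with the preset correlation (adjusted p under 0.05) and open circles did not. The cell cycle and matrix lists have the highest medians, from 3.08 to 3.76, and the fatty acid list the lowest of the metabolic lists, from -0.96 to -1.36; the median of the cardiomyocyte structural list in IRS2KO, -0.43, becomes 0.03 with quantile normalization.

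The 3 responses to TAC, each taken against sham libraries of its own genotype, were then set side by side. Log2 fold changes across the 13695 genes correlated with r = 0.94 between WT and IRS1KO (rho 0.909), 0.951 between WT and IRS2KO (rho 0.923) and 0.94 between the knockouts (rho 0.903); genes are not independent replicates. WT and IRS1KO shared 3451 raised and 3102 lowered genes, against 1258 and 1152 for independent lists of those sizes, and 8 genes went opposite ways. In all 3 genotypes 3236 genes, among them Sprr1a, Tnc and Nppa, rose and 2848, among them Ces1d and Atp2a2, fell. The first principal component, 69.7% of the variance, parted TAC from sham libraries, and the second, 6.87%, parted IRS1KO libraries from those of WT and IRS2KO. WT TAC replicate 2, at -3.02, and IRS2KO TAC replicates 4 (-0.42) and 1 (20.8) lay nearest to the sham libraries on the first component.

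**Figure D4:**
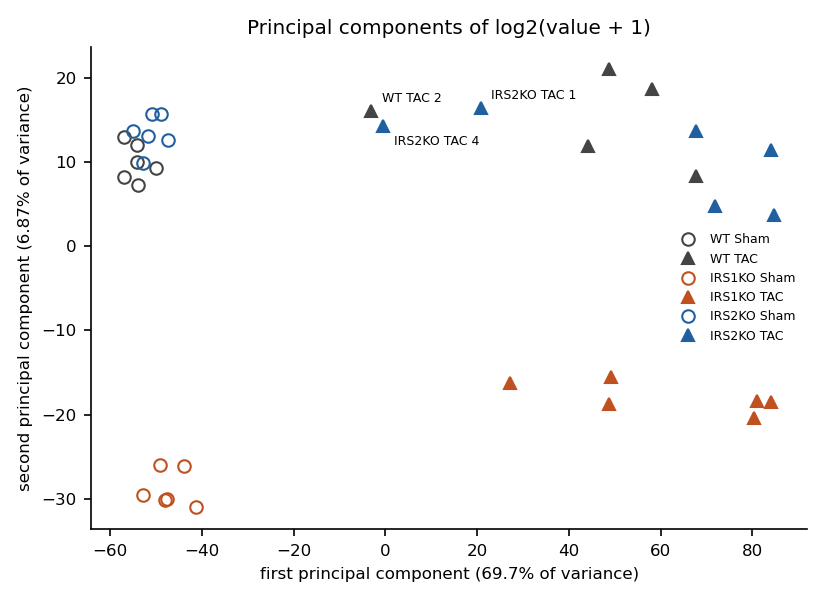
Each library on the first 2 principal components of the log2 values of 13695 genes; open circles are sham and triangles TAC libraries. TAC libraries lie to the right of all sham libraries, 3 of them between -3.02 and 20.8, and the IRS1KO libraries lie below 0 on the second component.

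The next comparison set IRS1KO against WT hearts in the absence of pressure overload; the groups differ in the floxed gene and in Cre as well as in Irs1. Nppa stood at 4045 ± 746 in IRS1KO and 594 ± 129 in WT sham hearts, 6.81-fold higher and above every WT library in 6 of 6 (limma log2 fold change 2.78, SE 0.22, adjusted p = 3.8e-11). The smooth muscle actin gene Acta2 was 2.82-fold, the growth factor gene Ccn2 2.23-fold, the chemokine receptor gene Cx3cr1 3.10-fold, Igf2 1.67-fold and Ifit2 1.59-fold higher in IRS1KO. The alpha-1A adrenergic receptor gene Adra1a was 3.38-fold lower, at 90.1 ± 21 against 305 ± 69.8. Some genes differed by more than Nppa: Plekha7 (chromosome 7, 116123485 to 116308376) stood at 458 ± 54.3 against 22.4 ± 4.87, and Nxpe4 (chromosome 9, 48162023 to 48400025) at 7.5 ± 2.95 against 236 ± 15.4. Trim12a (chromosome 7, 104299894 to 104315466) was listed at 0 in all 6 IRS1KO libraries and averaged 178 ± 30.6 in WT. Kcnj14 was 43.4-fold lower. Smaller differences were those of Dubr (5.41-fold), Zfp697 (5.33-fold), Ephb1 (5.22-fold) and Mboat2 (2.98-fold) on the higher side, and Ush1c (5.56-fold), Rab4a (4.49-fold) and Tmc7 (3.31-fold) on the lower side. Aqp6 was on in 4 of 6 IRS1KO libraries, at 535 to 682, and near 1 count in the other 2.

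Large differences were also measured for processed pseudogenes of ribosomal proteins, whose reads cannot be told from those of their parent genes with certainty. In IRS1KO sham hearts Rps3a3 stood at 40.8 ± 7.79 against 1107 ± 89.4 in WT and Rps3a2 at 14.9 ± 5.58 against 336 ± 26.7. The parent gene Rps3a1, which the rule did not select here and which was chosen after its values were seen, stood at 3689 ± 502 against 1429 ± 94.2. Rps13-ps1 was 11.2-fold higher.

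In all 274 genes were higher and 363 lower in IRS1KO sham hearts (396 and 232, 63.1% in place of 43.0% higher, with the same total per library). Among the fixed lists only fatty acid uptake and oxidation passed, downward, with none of its 26 members called and a median of -0.30 (adjusted p = 0.0049, adjusted p = 0.959 with an estimated correlation, and 0.0761 with quantile normalization). Without WT sham replicate 6 the number of lists past the threshold was 3, and without IRS1KO sham replicate 2, 3, 4 or 6 it was 2. The count of genes was 1483 when only these 12 libraries were fitted and 1795 with library weights.

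IRS2KO was compared with WT in sham hearts in the same way. No gene passed the threshold between IRS2KO and WT sham hearts (0 with limma, 534 at an unadjusted p under 0.05 where 685 would be expected by chance, 0 with edgeR and 2 with DESeq2). The collagen gene Col3a1 stood at 3273 ± 340 in IRS2KO and 2124 ± 291 in WT (log2 fold change 0.63, adjusted p = 0.955, above every WT library in 6 of 6), and the elastin gene Eln at 730 ± 89.9 and 491 ± 87.0 (adjusted p = 0.955). Fitted on these groups alone, both passed (adjusted p = 0.00652 and 0.0273), as 2 of 31 genes, and with library weights 23 genes passed. The extracellular matrix list was higher in IRS2KO with a median of 0.22, though none of its 27 members was called (adjusted p = 7.9e-05, and adjusted p = 0.924 with an estimated correlation). Fibroblast markers (adjusted p = 0.0279) and macrophage markers (adjusted p = 0.031) also passed upward with no member called (adjusted p = 0.924 with an estimated correlation for both), the macrophage call ended with the replicate number as a block (0.0502), and neither list held with every library left out in turn. Fibroblast markers missed without WT sham replicate 3 (0.0713) or 5 (0.081) or IRS2KO sham replicate 2 (0.161) or 4 (0.0509), and macrophage markers without WT sham replicate 2 (0.0971) or 5 (0.085) or IRS2KO sham replicate 1 (0.206), 2 (0.07) or 4 (0.0769), so that 1 list in place of 3 was left without WT sham replicate 5 or IRS2KO sham replicate 2 or 4. The count of genes was 1 without WT sham replicate 6.

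After TAC, IRS1KO hearts had more Nppa than WT hearts, 19972 ± 2936 against 8452 ± 2927, with every IRS1KO library above every WT library (limma log2 fold change 1.29, SE 0.24, adjusted p = 0.00054). Col11a1 was 9.94-fold higher, at 355 ± 205 against 35.7 ± 27.5, Acta2 1.79-fold and the adhesion molecule gene Cadm1 4.60-fold higher. Scn4b was 4.89-fold lower, at 24.8 ± 11.3 against 121 ± 46.5. Some of the genes that differed in sham hearts also differed here: Plekha7 (9.34-fold), Zfp697 (7.37-fold) and Dubr (4.08-fold) were higher, and Trim12a (10.2-fold, at 0.97 or less in all but replicate 5, at 78.3), Nxpe4 (9.47-fold), Kcnj14 (9.0-fold) and Ush1c (6.74-fold) lower. Rps13-ps1 was 11-fold higher and Rps3a3 28.8-fold and Rps3a2 21.8-fold lower, while Rps3a1 stood at 4699 ± 257 against 1827 ± 287.

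Between IRS1KO and WT hearts after TAC 8 lists passed with the preset correlation and 0 with an estimated one (adjusted p = 0.728 with an estimated correlation for each) or with fry, and few of their members were called. Fatty acid genes were lower in 6 of 26 cases, and in 23 adjusted over the list alone, with a median of -0.64 (adjusted p = 1.1e-12). Oxidative phosphorylation genes were lower in 1 of 41 cases, and in 37 adjusted over the list alone (median -0.40, adjusted p = 2.0e-13), and 1 of 17 tricarboxylic acid cycle genes was lower (median -0.36, adjusted p = 1.3e-06). Mitochondrial genome mRNAs were lower in 1 of 13 cases, and in 7 adjusted over the list alone (adjusted p = 0.00161, and 0.0947 with quantile normalization). The matrix list was higher, with 2 of 27 members called and a median of 0.51 (adjusted p = 7.3e-06). Cardiomyocyte structural genes and endothelial markers (both adjusted p = 0.00566) passed downward and cell cycle genes upward (8.7e-05), with 0, 1 and 1 members called, and 1, 1 and 0 adjusted over the list alone. The structural call was also lost with quantile normalization (0.0975). All 3 were lost without WT TAC replicate 2 (0.0638, 0.0638 and 0.144). Reads from the mitochondrial genome were 19.5% ± 3.22 of the total in IRS1KO and 23.4% ± 2.19 in WT TAC libraries.

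In all 276 genes were higher and 367 lower (653 and 283, 69.8% in place of 42.9% higher, with the same total per library, which moved the median gene by 0.14). The count was 228 when only the 11 libraries of these groups were fitted and 2183 with library weights; in simulated data for this comparison 44 of 167 calls were false with all groups in the fit and 4 of 102 with these groups alone. It was 369 without IRS1KO TAC replicate 2, 391 and 393 without WT TAC replicates 2 and 5, 1142 without WT TAC replicate 3 and 1313 without IRS1KO TAC replicate 5. Of the sham and TAC calls of IRS1KO against WT, 90 higher and 140 lower genes were shared, Irs1, Nppa and Plekha7 among them, against 5.52 and 9.73 for independent lists.

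No gene passed between IRS2KO and WT hearts after TAC (0 with limma, 931 at an unadjusted p under 0.05 where 685 would be expected by chance, and 0 with edgeR and with DESeq2). Pdk4 stood at 5759 ± 2298 in IRS2KO and 18425 ± 7382 in WT (log2 fold change -1.61, adjusted p = 0.509, below every WT library in 4 of 6), the kinase gene Sgk1 at 667 ± 155 and 1036 ± 194 (adjusted p = 0.509), the fatty acid transporter gene Cd36 at 14276 ± 4964 and 20140 ± 4441 (adjusted p = 0.562) and the metallothionein gene Mt1 at 2045 ± 575 and 3680 ± 1464 (adjusted p = 0.562). The glucocorticoid-responsive list was lower, with none of 8 members called and 4 adjusted over the list alone (median -0.62, adjusted p = 1.9e-07, adjusted p = 0.0889 with an estimated correlation, and 0.0305 with fry). Fatty acid genes were lower with 0 of 26 called and 4 adjusted over the list alone (median -0.43), oxidative phosphorylation genes with 0 of 41 (median -0.29) and tricarboxylic acid cycle genes with 0 of 17 (median -0.25), at adjusted p of 1.2e-15, 1.2e-15 and 8.9e-06 (adjusted p = 0.617 with an estimated correlation for each). Of the 11 lists past the threshold, 3 upward and 8 downward, the other 7 were lost without WT TAC replicate 2, at adjusted p from 0.0893 to 0.9996, and several of them also without another single library. Without the 3 TAC libraries nearest to sham, an alternative chosen after seeing the data, 405 genes passed, with Cd36 at 0.00904 and Pdk4 at 0.0386; without WT TAC replicate 2 alone 1 gene passed.

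The knockouts were also compared directly. In sham hearts 502 genes were higher and 635 lower in IRS1KO than in IRS2KO (780 and 318, 71.0% in place of 44.2% higher, with the same total per library). Nppa was 4.56-fold, Acta2 3.53-fold, Ccn2 2.24-fold, the neuronal activity gene Arc 6.04-fold and Ifit2 1.72-fold higher in IRS1KO. The orphan nuclear receptor gene Nr4a3 was 5.53-fold, the cell cycle inhibitor gene Cdkn1a 2.71-fold, Lyve1 of lymphatic endothelium and resident macrophages 2.08-fold, Eln 1.63-fold, the autophagy gene Gabarapl1 1.49-fold, Pdgfra 1.43-fold and Mtor 1.27-fold lower. Plekha7 (16.9-fold higher), Ephb1 (4.95-fold higher) and Trim12a, at 0 against 166 ± 20.7, differed as they did against WT, and Irs1 was 9.41-fold lower and Irs2 2.57-fold higher (adjusted p = 0.000257 and 0.0125). Fatty acid genes and glucocorticoid-responsive genes passed downward, with 2 of 26 and 3 of 8 members called, and interferon-stimulated genes upward with 2 of 14, or 3 up and 1 down adjusted over the list alone (each adjusted p = 0.0328, and adjusted p = 0.965 with an estimated correlation for each). The interferon call was lost with the same total per library (0.117), and all 3 with quantile normalization (0.19, 0.0799 and 0.0799). The number of lists was 0 without IRS2KO sham replicate 3 or 6 and 1 without IRS1KO sham replicate 2, 3, 5 or 6 or IRS2KO sham replicate 1, and the interferon list missed without IRS1KO sham replicate 1 (0.0645). The count of genes was 2148 with only these groups fitted and 2575 with library weights.

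After TAC 148 genes were higher and 175 lower in IRS1KO than in IRS2KO (238 and 147, 61.8% in place of 45.8% higher, with the same total per library). Zfp697 was 6.65-fold, Plekha7 6.87-fold, Cadm1 4.20-fold and Rps3a1 2.55-fold higher, and Nxpe4 9.76-fold, Rab4a 4.01-fold and the lipoprotein gene Apoe 3.66-fold lower, with Apoe at 1307 ± 339 against 4778 ± 2100. Trim12a was 9.58-fold lower, at 78.3 in IRS1KO replicate 5 and a mean of 0.19 in the other 5 libraries. Irs1 was 8.65-fold lower (adjusted p = 0.000426), and 14.1-fold lower without that replicate. Irs2 was 3.28-fold higher (adjusted p = 0.00948), but not with library weights (0.169), with only these groups fitted (0.121) or without the 3 TAC libraries nearest to sham (0.076). FoxO targets passed upward with 1 of 16 called and a median of 0.19 (adjusted p = 0.00706, and adjusted p = 0.788 with an estimated correlation). The count of genes was 140 with only these groups fitted and 494 without the 3 TAC libraries nearest to sham.

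**Figure D5:**
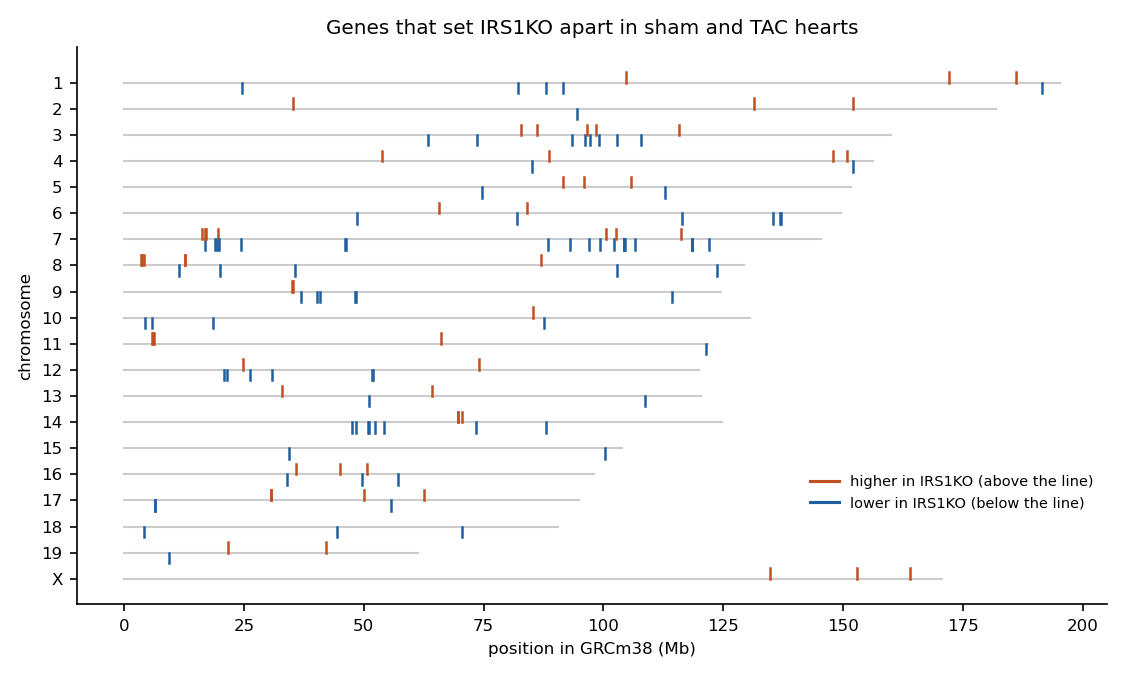
Positions in GRCm38 of the 150 genes that were called in 1 direction in all 4 comparisons of IRS1KO with WT or IRS2KO, 60 higher and 90 lower in IRS1KO. Ticks above a chromosome's line mark higher and ticks below it lower genes. The lower Gm47283 (chromosome Y) and the higher ENSMUSG00000095041 (scaffold JH584304.1) are not drawn. Chromosome 7 holds 28 of them, and 7.72% of all tested genes with a position, and chromosome 3 holds 13 of them.

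Whether the response to TAC itself differed between genotypes was tested as a difference of differences. Between IRS1KO and WT 5 genes were higher and 10 lower. Nxpe4 rose from 7.5 ± 2.95 to 19.9 ± 4.69 in IRS1KO and went from 236 ± 15.4 to 189 ± 19.1 in WT (difference 1.68 on the log2 scale, SE 0.24, adjusted p = 0.0007). Ssbp2 (difference 0.67, adjusted p = 0.0072) and the surface glycoprotein gene Cd200 (-0.86, adjusted p = 0.0285) also passed, but not with the same total per library (0.062 and 0.0636), and Cd200 not without WT sham replicate 2 (0.0522) or IRS1KO TAC replicate 4 (0.0516). Of 10 lists past the threshold with the preset correlation, 3 upward and 7 downward, 0 passed with an estimated one or with fry. Fatty acid, oxidative phosphorylation and endothelial lists passed downward (adjusted p = 0.000189, 7.9e-10 and 0.00208) and glycolysis upward (0.00476) with any 1 library left out, with 0, 0, 1 and 0 members called, and 0, 0, 2 and 1 adjusted over the list alone (adjusted p = 0.799 with an estimated correlation for each). The other 6 each lost the call without at least 1 library: matrix (0.0179) and cell cycle genes (0.0488) upward, and tricarboxylic acid cycle (0.00208), interferon-stimulated (0.015), cardiomyocyte structural (0.0432) and mitochondrial genome genes (0.0432) downward (adjusted p = 0.799 with an estimated correlation for each). The gene count was 7 with the same total (4 higher, 3 lower), 25 without the 3 TAC libraries nearest to sham, 54 with DESeq2 and 192 with library weights. Without WT sham replicates 1 to 5 in turn it was 6, 2, 5, 4 and 7, without WT TAC replicate 1 it was 3, without IRS1KO sham replicates 2 and 6 it was 9 and 3, and without IRS1KO TAC replicates 2 to 5 it was 6, 9, 2 and 53.

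Between IRS2KO and WT no gene differed in its response (0 with limma, 713 at an unadjusted p under 0.05 where 685 would be expected by chance, and 0 with edgeR and with DESeq2; 4 without the 3 TAC libraries nearest to sham). With the preset correlation 7 lists passed downward, and 0 did with an estimated one or with fry. Of the 7, the FoxO targets (median -0.28), the glucocorticoid-responsive genes (-0.98), the fatty acid genes (-0.39), the oxidative phosphorylation genes (-0.29) and the tricarboxylic acid cycle genes (-0.28) passed with any 1 library left out. Their adjusted p was 0.000216, 2.0e-06, 9.4e-09, 9.4e-09 and 0.000155 in that order, against adjusted p = 0.165 with an estimated correlation for the glucocorticoid-responsive genes and 0.818 for the others. No member of these lists was called, and adjusted over the list alone 2 glucocorticoid-responsive genes and 1 fatty acid gene were.

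Between IRS1KO and IRS2KO 36 genes were higher and 20 lower in the difference of responses. Acta2 stood at 5603 ± 887 in IRS1KO sham and 5274 ± 937 in IRS1KO TAC hearts, and went from 1588 ± 206 to 4419 ± 1030 in IRS2KO (difference -1.54, SE 0.22, adjusted p = 0.00042). Mgp, an inhibitor of vascular calcification, rose from 927 ± 193 to 2218 ± 184 in IRS1KO against 1467 ± 122 and 1758 ± 314 in IRS2KO (difference 1.03, SE 0.19, adjusted p = 0.00725). The p53 target gene Trp53inp1 (1.46), Nxpe4 (1.55), Epb41l3 (0.99) and the glutamine synthetase gene Glul (0.83) differed upward, and Plekha7 (-1.29), Cd200 (-1.12) and Phyhip (-0.95) downward. FoxO targets (2 of 16 called, 3 adjusted over the list alone; adjusted p = 1.3e-05) and glucocorticoid-responsive genes (0 of 8 called, 4 adjusted over the list alone; 0.000102) passed upward and interferon-stimulated genes downward with 0 of 14 called (0.000681; adjusted p = 0.574, 0.437 and 0.988 with an estimated correlation). Insulin and IGF signalling components also passed upward, with 0 of 32 called and 0 adjusted over the list alone (median 0.11, adjusted p = 0.0154, adjusted p = 0.723 with an estimated correlation, 0.154 with quantile normalization and 0.0509 without IRS1KO TAC replicate 5). None of the 4 passed with fry. The gene count was 21 with only these groups fitted, 25 with the same total (9 higher, 16 lower), 26 without a filter, 34 with quantile normalization (18 higher, 16 lower), 138 with library weights, 157 with DESeq2 and 360 without the 3 TAC libraries nearest to sham. It fell to between 17 and 37 without any 1 of IRS1KO sham replicates 1, 2 and 5, IRS1KO TAC replicates 1 to 4, IRS2KO sham replicates 1 and 3 to 6 or IRS2KO TAC replicates 4 to 6, and was 88 without IRS2KO sham replicate 2 and 180 without IRS1KO TAC replicate 5.

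The knockouts were set side by side against the WT libraries they share. In sham hearts the log2 fold changes of IRS1KO and IRS2KO against WT correlated with r = 0.106 (rho 0.095) across genes, where 100 simulations of unchanged groups against the same controls gave 0.498 on average (0.468 to 0.529). The covariance was 0.00694 against a simulated 0.0132, a difference of -0.00623. With the WT libraries split between the 2 comparisons, r had a median of -0.048. After TAC r was 0.562 (rho 0.644) against a simulated 0.549 (0.521 to 0.569), the covariance 0.0467 against 0.0297, a difference of 0.0171, and r over 10 splits of the WT libraries had a median of 0.175 and ranged from -0.034 to 0.309. The simulations drew each gene independently. They hold no difference between libraries in the size of the TAC response, such as that of WT TAC replicate 2. The higher covariance therefore cannot be read as an effect that the knockouts share. No calls could be overlapped, since IRS2KO against WT had 0 (534 and 931 at an unadjusted p under 0.05 in sham and TAC, limma).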

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

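The tests of clustering along chromosomes, of pseudogenes, of exchanged labels and of IRS1KO TAC replicate 5 were chosen after the result they address was seen; the others in this part were planned before it.

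Among 132 groups of values tested for a library far from the rest, 10 had one, where chance alone gives about 1 in 20, or 6.6. Irs1 was 80.3 in IRS1KO TAC replicate 5, against 26.7 in the next library, and Trim12a was 78.3 there against 0.97. Irs2 was 564 in WT sham replicate 2, against 195. Kcnj14 was 12.1 in the same library, against 247 in the next lowest. Ces1d was 1783 in IRS1KO sham replicate 1, against 1341, and 183 in IRS2KO TAC replicate 4, against 38.2. Sprr1a was 10.7 in WT sham replicate 6, against 2.11, and 0 in IRS2KO sham replicate 5, against 2.16. Rps3a2 was 285 in WT sham replicate 6, against 336. Aqp6 was 1.03 in IRS2KO TAC replicate 1 and 0 in the other libraries of that group.

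A difference in the TAC response was found for 12 results by the test of the difference itself (limma). For IRS1KO minus WT these were Nxpe4 (1.68), Ssbp2 (0.67) and Cd200 (-0.86). For IRS1KO minus IRS2KO they were Nxpe4 (1.55), Trp53inp1 (1.46), Mgp (1.03), Epb41l3 (0.99), Glul (0.83), Acta2 (-1.54), Plekha7 (-1.29), Cd200 (-1.12) and Phyhip (-0.95), all on the log2 scale.

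The first pattern is the set of 150 genes, Plekha7, Trim12a and Nxpe4 among them, that differed in 1 direction in all 4 comparisons of IRS1KO with WT or IRS2KO, 28 of them on chromosome 7. That chromosome holds 7.72% of all tested genes with a position. As for reads shared with pseudogenes, 18.7% of the genes are annotated as pseudogenes, Rps3a2, Rps3a3 and Rps13-ps1 among them. This share was not set beside that of all tested genes. It does not measure shared reads, since a parent gene such as Rps3a1, also among the 150, is not annotated so. Shared reads therefore stay open as a cause. A strain difference between the lines may account for part of it: 36.7% of the genes had another within 1 Mb, against a median of 20% and a highest value of 34% in 1000 random sets of like expression and 27.3% among leading TAC genes. Alleles still segregating in the IRS1KO line stay open, with 4 genes parted by an 8-fold gap within IRS1KO sham libraries and 1 each within WT and IRS2KO sham libraries. The 4 genes (Tmprss13, Aqp6, BC002163 and Plet1os) are not among the 150, so their count says little on the pattern itself. Loss of Irs1 in cardiomyocytes cannot be told apart from the line, because 0 libraries came from floxed Irs1 mice without Cre.

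The second pattern is the spread of TAC libraries along the first principal component, with WT TAC replicate 2 and IRS2KO TAC replicates 4 and 1 nearest to sham. Sequencing depth is argued against, with r = -0.0772 between the component and recovered reads over 17 TAC libraries (permutation p = 0.769, rho = -0.0196 with permutation p = 0.944, r = 0.0191 without the 2 libraries farthest from the median depth, and -0.768, 0.452 and 0.0338 within WT, IRS1KO and IRS2KO). Exchanged sham and TAC labels are argued against, since 100% of 40 raised stress and matrix genes lay above every sham library in each of the 3. TAC RNA mixed with sham RNA cannot be told apart from a milder response: the fractions of the response of stress and matrix genes differed, with an interval that excludes 0, in 1 of the 3 libraries (0.528 and 0.772 in WT TAC replicate 2). The fractions were taken on the log2 scale, on which mixing need not give equal fractions to genes with unequal changes. Such a difference therefore does not decide on mixing. The pressure reached in each mouse was not analysed here, so no biological explanation was tested.

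The third pattern is that IRS1KO TAC replicate 5 lay nearer to WT at part of the genes that set IRS1KO apart. The highest fractions of the way to WT among the 150 genes were those of Tnfrsf10b (0.841, chromosome 14), Ap1s2 (0.743, chromosome X), Coq7 (0.732, chromosome 7), Zfp697 (0.678, chromosome 3) and Rps15a-ps3 (0.643, chromosome 4). Trim12a (0.578), Plekha7 (0.404) and Ush1c (0.0216), all on chromosome 7, were lower. Ush1c starts at 46195350, beside Gm9860 (-0.0646) and far from Trim12a and Plekha7. Near Trim12a, Trim5 (0.405), Trim30d (0.314) and Gm1966 (0.233) also lay partway to WT, and Trim34a (0.141) less so. Coa4 (-0.108, at 100537071) and Itpripl2 (-0.312, at 118485111) did not, while Cadm4 (0.552, at 24482023) did. RNA of a WT heart mixed into the library is argued against by the genes on other chromosomes, whose median fraction of the way to WT was 0.0108 (interval -0.0149 to 0.0566, 122 genes). A mixed strain background on chromosome 7 in that mouse is a candidate explanation for part of it: the median fraction there was 0.318 over 28 genes, higher by 0.307 (interval 0.0598 to 0.4, or 0.0289 to 0.388 without Trim12a, the gene that prompted the test). The difference was negative in TAC replicates 4 (-0.121, interval -0.171 to -0.0424) and 6 (-0.0549, -0.138 to -0.00346), whose reference holds replicate 5, and with replicate 5 out of the reference both intervals include 0 (-0.111 to 0.0066 and -0.0612 to 0.048). These intervals take the 28 genes as independent. Genes close together on 1 chromosome are not, so the intervals are likely too narrow. In replicate 5 Coq7 (575) and Cadm4 (88.2) lay near their IRS1KO sham means (561 and 95.8), while Plekha7 (236, sham 458) did not. Tnfrsf10b, Ap1s2 and Zfp697, and Irs1 on chromosome 1 (0.387 of the way to WT), are left open by a mixed background on chromosome 7. For Rps15a-ps3 the chromosome does not decide, since reads of a processed pseudogene cannot be told from those of its parent gene with certainty. Rps15a-ps8 (0.589), Rps15a-ps7 (0.543), Rps15a-ps6 (0.279) and Rps15a-ps5 (0.203) also lay partway to WT, while Rps3a2 (-0.0121) and Rps3a3 (-0.00351) did not. Such pseudogenes count among the 122 genes on other chromosomes. Replicate 5 also lay nearest to sham of its group on the first component, at 27.2 against 48.6 or more. A fraction of the way to WT can thus reflect a smaller TAC response, which was not tested. Tnfrsf10b (83.3), Ap1s2 (633) and Zfp697 (333) lay toward their IRS1KO sham means (76.7, 458 and 210). Irs1 (80.3), Trim12a (78.3) and Rps15a-ps3 (28.7) lay beyond theirs (25.9, 0 and 49.8). So did Trim5 (15.9, sham 2.14), Trim30d (26.8, sham 1.26) and Gm1966 (17.8, sham 1.405), while Trim34a (14.9, sham 19.3) did not.

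Each count was also set beside 100 splits of the same libraries, the real one included. For genes, no other split reached the real count for TAC against sham in WT (7515 calls, highest other 5875, 1 split as large), IRS1KO (8777, 7173, 1) and IRS2KO (8546, 5604, 1). Nor did any for IRS1KO against WT in sham (637, 99, 1) and against IRS2KO in sham (1137, 95, 1). These counts argue against chance but do not exclude it. The smallest possible share with 100 splits is 1 in 100, with no adjustment over the contrasts. In TAC against sham, other splits can keep part of the TAC effect, and the real gene counts lay above all of them. For IRS1KO against WT after TAC (643, 1753, 3) few splits were as large, with no adjustment over the contrasts. The same held for the differences of the TAC response IRS1KO minus WT (15, 224, 3) and IRS1KO minus IRS2KO (56, 1607, 3). Splits with several times the real count there point to a structure of the TAC libraries other than the genotype. Such a structure can give counts of this size, so these counts cannot decide on chance. Chance cannot be excluded for IRS1KO against IRS2KO after TAC (323, 4030, 15 splits as large). For IRS2KO against WT in sham, after TAC and in the response limma called 0 genes (534, 931 and 713 at an unadjusted p under 0.05, 0 with edgeR and 2, 0 and 0 with DESeq2), so all 100 splits are at least as large by construction and say nothing on chance. The highest other counts there were 3, 4330 and 2416, and what set those splits apart was not tested.

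For gene lists few splits were as large only for TAC against sham in IRS1KO (19 lists, highest other 20, 3 splits as large), with no adjustment over the 12 contrasts. More were as large for TAC against sham in WT (18, 21, 14) and IRS2KO (20, 21, 8). These 3 counts cannot decide on chance. A split that shares the TAC libraries unequally between its groups keeps part of the TAC effect (median other counts 11 in WT, 11 in IRS1KO and 12 in IRS2KO). Chance cannot be excluded for IRS1KO against WT in sham (1, 6, 78) and after TAC (8, 19, 73), or for IRS2KO against WT in sham (3, 5, 15) and after TAC (11, 22, 61). Nor can it be for IRS1KO against IRS2KO in sham (3, 6, 23) and after TAC (1, 21, 100), or for the differences IRS1KO minus WT (10, 19, 38), IRS2KO minus WT (7, 19, 67) and IRS1KO minus IRS2KO (4, 20, 84). Other splits of the libraries often called as many lists as the genotypes did, which points to list members that move together between libraries.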

How the results depend on the processing

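The alternative without the 3 TAC libraries nearest to sham, WT TAC replicate 2 and IRS2KO TAC replicates 1 and 4, was chosen after seeing the data; every other setting here was planned. Of 270 results for single genes taken under the rule, 251 passed the threshold, and 245 of these did so in each of the 12 alternatives, and with any 1 library left out, wherever they had a test, as did all 165 of TAC against sham. The rule favoured large called changes, so these numbers say little on the other calls. At a mean of at least 50 only 256 of the 270 had a test, and with DESeq2 266. None changed direction; 3 of 3354 lost and 1 gained the call with 1 library left out. Except where stated, the cause of a change was not tested.

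Fitting only the groups in the contrast, with fewer libraries to estimate the spread, gave 1483 genes for IRS1KO against WT in sham, 31 for IRS2KO against WT in sham, 228 for IRS1KO against WT after TAC, 2148 and 140 for IRS1KO against IRS2KO in sham and after TAC, and 21 for the difference IRS1KO minus IRS2KO. Library weights gave 1795, 23, 2183 and 2575 for the first 3 of these and IRS1KO against IRS2KO in sham, and 192 and 138 for the differences IRS1KO minus WT and IRS1KO minus IRS2KO. DESeq2 gave 2 for IRS2KO against WT in sham and 54 and 157 for those differences. Without a filter the counts were 1 and 2 for IRS2KO against WT in sham and after TAC and 26 for IRS1KO minus IRS2KO. The same total per library gave 7 and 25 for the 2 differences, and quantile normalization 34 for the second. With quantile normalization 42.4%, 44.0% and 43.8% of calls in TAC against sham were upward in WT, IRS1KO and IRS2KO. For IRS1KO minus WT the same total left 57.1% of calls upward in place of 33.3%, and for IRS1KO minus IRS2KO 36.0%, and quantile normalization 52.9%, in place of 64.3%. Without the 3 TAC libraries nearest to sham the counts were 405 for IRS2KO against WT after TAC, 494 for IRS1KO against IRS2KO after TAC, and 25, 4 and 360 for the differences IRS1KO minus WT, IRS2KO minus WT and IRS1KO minus IRS2KO.

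Gene lists depended most on the correlation between members: with an estimated correlation and all libraries 0 lists passed in each of the 12 contrasts, and fry called 0 in every genotype comparison but IRS2KO against WT after TAC, with 1. For IRS1KO against WT in sham 0 lists passed with quantile normalization and 2 with the same total, and for IRS1KO against IRS2KO in sham 0 with quantile normalization. For IRS1KO against IRS2KO after TAC 7 passed with the same total and 11 without the 3 TAC libraries nearest to sham; that setting gave 13 and 11 for the differences IRS2KO minus WT and IRS1KO minus IRS2KO. Without those libraries the direction turned for IRS1KO against IRS2KO after TAC in the extracellular matrix (adjusted p = 0.00882), cell cycle (0.0129), fatty acid (0.0144), oxidative phosphorylation (0.000758) and tricarboxylic acid cycle (0.0207) lists, for IRS1KO minus WT in the cell cycle list (0.669), and for IRS1KO minus IRS2KO in the cell cycle (0.00234), oxidative phosphorylation (0.000347) and mitochondrial genome (0.0238) lists. These are values at the preset correlation. With an estimated one and without those libraries, 2 lists passed for TAC against sham in WT, extracellular matrix and cell cycle (both 0.0426), and 0 in each of the other 11 contrasts.

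With the replicate number as a block, no single-gene call of 270 changed. Of list calls 4 were lost: calcium handling in IRS1KO after TAC (0.0584), fibroblast markers in IRS2KO after TAC (0.0531), macrophage markers in IRS2KO against WT sham (0.0502) and erythroid markers in IRS2KO against WT after TAC (0.0694). The block added 3: stress genes in IRS1KO against WT after TAC (0.0457), cell cycle in the difference IRS2KO minus WT (0.038) and oxidative phosphorylation in IRS1KO against IRS2KO after TAC (0.0266), which then had 2 lists. The labels do not say that a number pairs libraries. Of 85 same-number pairs 38 had correlated deviations over 0.1 (median 0.0878, other pairs -0.0242), in 0 pairs of groups were all over 0.1, and 71 of 170 comparisons had the best match at the library's own number. The block gave 935 genes for IRS1KO against WT after TAC, against 643 without it.

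Leaving out 1 library gave 0 to 1 genes for IRS2KO against WT in sham and after TAC, 369 to 1313 for IRS1KO against WT after TAC, and 2 to 53 and 17 to 180 for the differences IRS1KO minus WT and IRS1KO minus IRS2KO. It gave 1 to 3 lists for IRS1KO against WT and 1 to 4 for IRS2KO against WT in sham, 0 to 3 and 1 to 10 for IRS1KO against IRS2KO in sham and after TAC, and 6 to 11 and 4 to 8 for those differences. The cell cycle list ranged from 2.7e-07 to 0.9996 for IRS2KO against WT after TAC, where it turned direction without WT TAC replicate 2, and from 0.00232 to 0.754 for IRS1KO minus WT. Correlations of the TAC responses across genes ranged from 0.934 to 0.942 for WT and IRS1KO, 0.94 to 0.955 for WT and IRS2KO and 0.933 to 0.945 for IRS1KO and IRS2KO. They were 0.952, 0.961 and 0.949 at a mean of at least 50, and 0.943 for the last pair without the 3 TAC libraries nearest to sham.

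A sex covariate was not run, since all libraries expressed Y-linked genes. At 11707111 to 14609467 reads per library the levels of genes near the filter rest on few reads.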

Other observations

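The test of a covariate given here was planned before its result was seen, and the genes parted within a group were chosen after their values were seen.

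A few genes were on in some libraries of a group and nearly off in others. Aqp6, which encodes an aquaporin (chromosome 15, 99601400 to 99605477 in GRCm38), stood at 682, 666, 603 and 535 in 4 IRS1KO sham libraries and at 2.15 and 1.13 in the other 2. BC002163 (chromosome 16) stood at 947, 873 and 693 in 3 IRS1KO sham libraries and at 30.6, 20.7 and 20.7 in the rest. The serine protease gene Tmprss13 stood at 139, 73.4 and 70.3 against 6.21, 5.18 and 2.91, and Plet1os at 80.2, 61.4 and 52.0 against 2.91, 1.04 and 1.03, both on chromosome 9. The potassium channel gene Kcnj14 (chromosome 7, 45816460 to 45824782) stood at 329, 270, 239 and 237 in 4 IRS2KO sham libraries and at 16.7 and 12.3 in 2, and the peptide transporter gene Slc15a2 at 94.8, 70.3 and 48.1 in 3 WT sham libraries and at 3.16, 2.91 and 0 in the others.

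As a hypothesis, the 11 gene lists shifted at the preset correlation between IRS2KO and WT after TAC, where no gene passed with limma (931 at an unadjusted p under 0.05, and 0 with edgeR and with DESeq2), may come from libraries that differ in the size of their TAC response. With an estimated correlation 0 of the 11 passed (smallest adjusted p = 0.0889), and the covariate was tried at the preset correlation only. With the first principal component as a covariate, 5 of the 11 were still past the threshold in the same direction: fatty acid oxidation (adjusted p = 2.1e-18), oxidative phosphorylation (9.0e-13), glucocorticoid-responsive genes (9.5e-07), the tricarboxylic acid cycle (0.00136) and FoxO targets (0.0261). The extracellular matrix, cell cycle, endothelial, erythroid, stress and mitochondrial genome lists were not (0.104, 0.165, 0.115, 0.165, 0.242 and 0.129). With the covariate 3 other lists passed: macrophage markers (0.00317), cytokines (0.00415) and smooth muscle markers (0.0207). The outcome lay between those set in advance, at most 3 lists if the response size were the cause and at least 9 if not, so the test leaves it open, and the component itself holds part of any genotype effect.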
